A study of Mus musculus with 9 samples.

How the data were processed

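RNA-seq of polyA RNA was used from 9 libraries in 3 groups of 3: steady-state lymph node FRC, steady-state RPF and RPF after macrophage depletion. Every library pooled 2 mice, so a library and not a mouse is the unit of replication, and 12 mice were used in all. The deposited table gives raw read counts per Ensembl gene, which were used here as they are. It also holds the authors' normalized values, fold changes and p-values, which were not used here. The submitters' processing notes name cutadapt 1.10, Bowtie2 2.2.8, STAR 2.5.3a and HTSeq 0.6.1p1 and the build mm10. The strand setting and the annotation release are not given in the sources used here. The deposited table also gives a median transcript length in bases per gene, which was used only to look for length bias. The 24 unused per-sample columns hold the normalized values of all libraries and the raw counts of 2 further libraries, which were not used here either.

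Counts of 27370 genes were read, 881 of them with no count in the 9 libraries, and 13 symbols stood on more than 1 row. After the filterByExpr filter 15103 genes were tested. The model was fitted in R 4.3.3 with edgeR 4.0.16, with TMM scaling, a term for each of the 3 groups, the robust quasi-likelihood fit and 6 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The comparisons were depleted against steady-state RPF, and steady-state RPF against steady-state FRC. The lymph nodes and the spleens at steady state came from 6 untreated mice each, of 12 mice in all with the 6 treated ones, so FRC and steady-state RPF share mice. Which of their libraries share mice is not given in the sources used here. Among them, only FRC replicate 1 and RPF steady replicate 1 lacked Y-linked reads (0 and 1 counts), so these may share mice. No paired analysis was made, and the test treats these libraries as independent.

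Before the data were examined, 18 response lists and 16 lists of other cell types were fixed, together with the tests, the rule for named genes and the other settings to try. In each comparison the 31 lists with at least 3 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and adjusted together. Of the list genes, 17 were not in the table. Named genes were, for each comparison, the 5 called protein-coding genes with the largest rise and the 5 with the largest fall, at a mean of at least 10 CPM in the higher group and with no overlap between the libraries of both groups. Gene models, immunoglobulin, T cell receptor, haemoglobin and sex-linked genes were left out of that part. The rule also named the 2 called genes with the smallest p in each response list with at least 3 called genes, all genes behind the sort or the study question, and the 2 most abundant genes of each list of another cell type. Further list members are named as examples of their list's count, and not every gene under the rule is given in the text.

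Levels are TMM-normalised CPM. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio is given with its 95% counting interval. Shares of counts were compared by an exact two-sided permutation test of 3 against 3 libraries, whose smallest p is 0.1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

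The alternatives were RLE and upper quartile scaling, no filter, a filter of 1 CPM in all libraries of a group, DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, no robust prior, a fit of the compared groups alone, an estimated correlation and fry for the lists, and leaving out each library in turn. A term for Y-linked reads and the removal of other cell types' genes were added after seeing the data. The model was tested on simulated data in which 100 genes changed 2-fold and 100 changed 4-fold in each comparison. It recovered 7% of 2-fold and 51% of 4-fold changes between the RPF groups, and 5% and 38% between RPF and FRC, with 0 in the wrong direction and between 1 and 2 false calls. The simulation changed a far smaller share of genes than the 21% and 25.9% called in the 2 real comparisons. These recovery rates may therefore not carry over to the data. A simulated 2-fold rise of the NF-kB and TNF response list was called by camera at an adjusted p of 3.26e-58, with 1 other list called. The simulated genes were drawn independently, while the correlation estimated for this list after depletion was 0.114. This simulation therefore does not test camera on correlated genes.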

Results

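The series measured polyA RNA of sorted mouse fibroblasts in 9 libraries that fall into 3 groups of 3. The first group holds fibroblastic reticular cells (FRC), the reticular stroma of lymph nodes, at steady state. The second holds red pulp fibroblasts (RPF) of the spleen, marked by tdTomato in a Wt1 lineage reporter, at steady state. The third holds RPF of mice whose macrophages had been depleted with diphtheria toxin, which kills cells that carry the toxin receptor under CD64 control. Each library pooled 2 mice, and 45000 cells were sorted per group from 6 mice. The total count per library ran from 25414645 in RPF steady replicate 3 to 43879806 in FRC replicate 3. Levels are given as TMM-normalised CPM, as mean ± SD over the 3 libraries of a group. Coordinates are those of the deposited table, for build mm10.

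The 3 groups separated cleanly. Across genes, the correlation of log2 CPM between libraries of the same group ran from 0.879 to 0.921. It ran from 0.845 to 0.862 between depleted and steady-state RPF, and from 0.686 to 0.724 between FRC and steady-state RPF. Genes are not independent replicates, so no p is attached to these values. The first principal component held 49.3% of the variance and the second 17.5%. Y-linked genes had 0 counts in FRC replicate 1 and 1 count in RPF steady replicate 1, where Xist was at 215 and 190 CPM. The other 7 libraries had between 2285 and 6101 Y-linked counts.

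**Figure D1:**
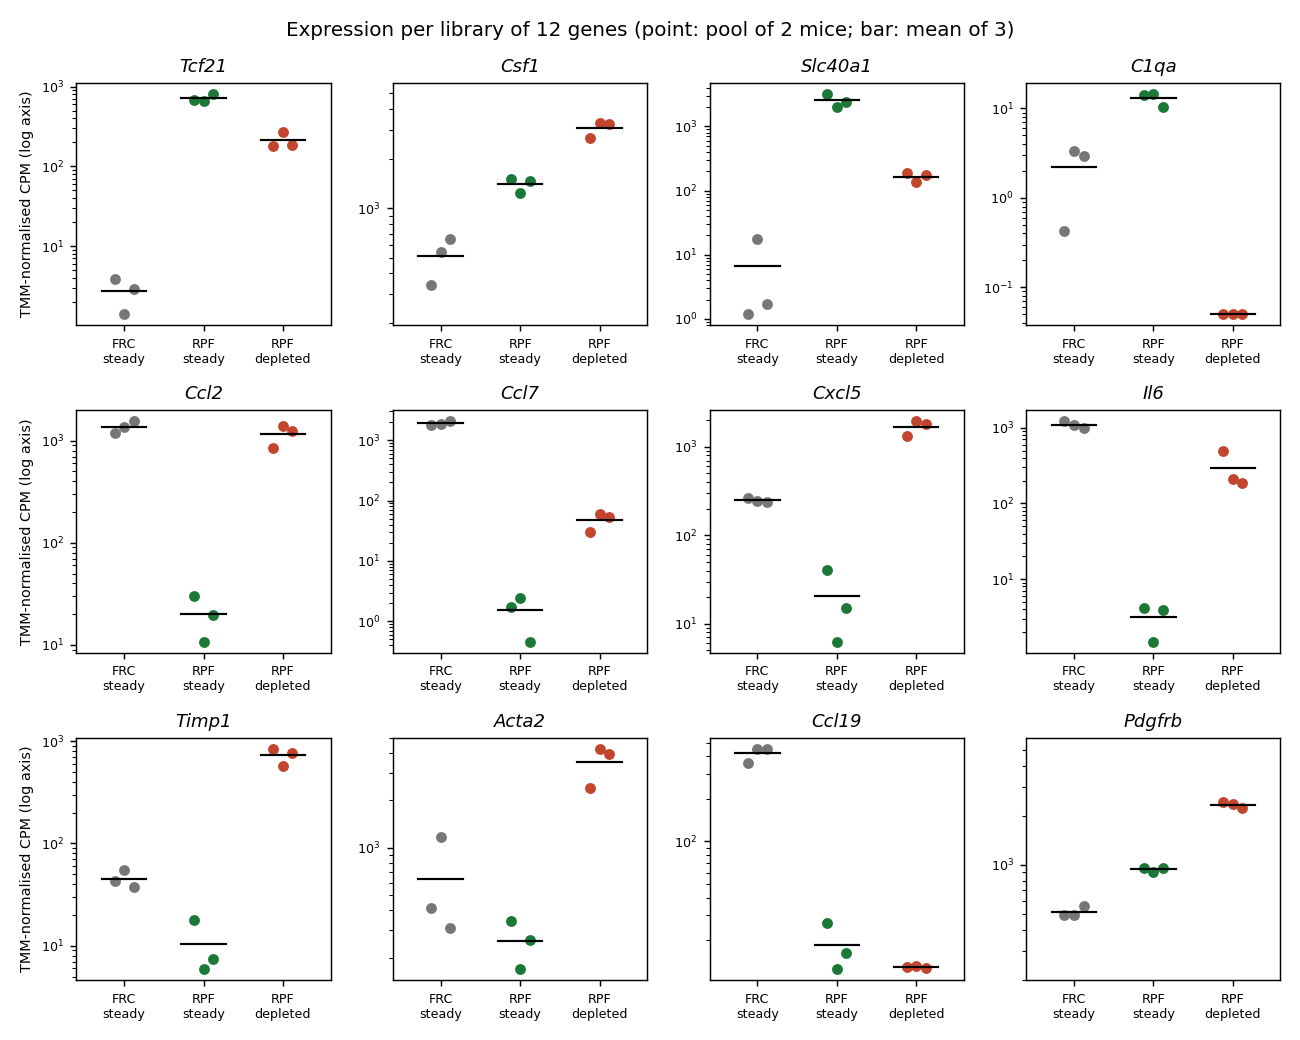
Expression of 12 genes in each library, as TMM-normalised CPM on a log axis, with points for libraries of 2 pooled mice and bars for the mean of 3. Values under 0.05 CPM are drawn at 0.05, as for C1qa in depleted RPF; Ccl2 averaged 20.3 CPM in steady-state RPF and 1167 CPM in depleted RPF.

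Comparing depleted with steady-state RPF asks how red pulp fibroblasts respond when macrophages are lost. Depleted RPF had far more mRNA for chemokines that attract monocytes and neutrophils. Ccl2, the main ligand of the monocyte receptor CCR2, rose 57.6-fold, from 20.3 ± 9.78 to 1167 ± 283 CPM (n = 3), and Cxcl5 rose from 20.8 ± 17.9 to 1692 ± 321 CPM. Csf1, the growth factor on which tissue macrophages depend, was already at 1404 ± 142 CPM and rose 2.19-fold to 3082 ± 362 CPM. Genes of the NF-kB response rose as well, as did the acute phase and contractile lists, whose calls were lost at adjusted p = 0.0883 and adjusted p = 0.562 with an estimated correlation. The immediate early and dissociation stress list was also called higher (camera adjusted p = 0.0019, and adjusted p = 0.768 with an estimated correlation). Transcription factors of the spleen primordium fell (camera adjusted p = 0.00428; adjusted p = 0.0883 with an estimated correlation), and markers of red pulp macrophages were almost gone from the sorted cells. In all, edgeR called 1671 genes higher and 1505 lower of 15103 tested, and 1088 and 1185 of these were beyond 2-fold.

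Of the 11 tested myeloid chemoattractant genes, 6 rose and 0 fell, and these counts were the same when adjusted over the list alone (camera adjusted p = 9.03e-11; adjusted p = 0.0386 with an estimated correlation). Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) rose by 5.85 on the log2 scale (SE 0.41, edgeR adjusted p = 4.84e-05). Ccl7, also a CCR2 ligand, rose 30.3-fold from 1.53 ± 0.987 to 47.9 ± 15.9 CPM (edgeR adjusted p = 0.000241). The neutrophil attractants Cxcl1 and Cxcl2 rose from 51.1 ± 29.2 to 955 ± 148 CPM and from 2.09 ± 0.819 to 45.3 ± 10.8 CPM, with edgeR adjusted p values of 0.000115 and 6.2e-05. The depleted libraries lay above the steady-state libraries in 3 of 3 for each of these genes. Beside this rise, the summed share of the red pulp macrophage markers ran from 0.000403% to 0.00188% of counts in the depleted and from 0.0277% to 0.0315% in the steady-state RPF libraries, the highest depleted value being that of replicate 1. The exact two-sided permutation p of that difference was 0.1, the smallest that 3 against 3 libraries allow.

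The NF-kB and TNF response list showed the most uniform change, with 17 of 18 tested genes higher and 0 lower, and the same counts when adjusted over the list alone (camera adjusted p = 8.16e-35; adjusted p = 0.00651 with an estimated correlation). Sod2, a mitochondrial superoxide dismutase induced by NF-kB, rose 22.1-fold from 92.3 ± 8.71 to 2039 ± 197 CPM (edgeR adjusted p = 8.47e-06). Ptgs2, the inducible cyclooxygenase, rose 17.3-fold to 53.3 ± 0.944 CPM, also at an edgeR adjusted p of 8.47e-06. The cytokines Il6 and Lif rose to 294 ± 167 and 350 ± 168 CPM from 3.20 ± 1.48 and 23.2 ± 6.71 CPM. The feedback inhibitors Nfkbia and Tnfaip3 rose to 1172 ± 89.7 and 716 ± 177 CPM from 215 ± 86.2 and 97.9 ± 36.6 CPM. Irf1 was at 265 ± 73.1 CPM after depletion and 230 ± 20.2 CPM at steady state (edgeR adjusted p = 0.65). The list shares Ccl2 and Cxcl1 with the chemoattractants. The neutrophil marker genes held 0.00506%, 0.00076% and 0.000253% of counts in depleted replicates 1, 2 and 3, and 0.0106%, 0.0422% and 0.00563% in steady-state replicates 1, 2 and 3, at an exact permutation p of 0.1.

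In the acute phase and IL-6 response list, 10 of 14 tested genes rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 1.02e-06). With an estimated correlation its call was lost, at adjusted p = 0.0883 with an estimated correlation. Timp1, an inhibitor of matrix metalloproteinases, rose 69.9-fold from 10.4 ± 6.46 to 727 ± 139 CPM (edgeR adjusted p = 6.45e-05). Saa3, an acute phase apolipoprotein, rose from 0.0455 ± 0.0162 to 12.9 ± 5.31 CPM (edgeR adjusted p = 0.000107, and 0.056 in limma-voom). Lcn2, a siderophore-binding protein, rose from 8.85 ± 8.70 to 1094 ± 60.9 CPM, and Cebpb from 151 ± 31.2 to 632 ± 51.2 CPM. The member that fell was Il6st, the shared receptor subunit of the IL-6 family, from 1306 ± 115 to 699 ± 78.9 CPM (edgeR adjusted p = 0.00163).

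The contractile list had 7 of 12 tested genes higher and 0 lower, unchanged when adjusted over the list alone (camera adjusted p = 0.00293; adjusted p = 0.562 with an estimated correlation). Acta2, smooth muscle actin, rose 13.9-fold from 255 ± 85.1 to 3536 ± 1010 CPM (edgeR adjusted p = 0.00128), and Tagln, an actin-binding protein of smooth muscle, rose 8.66-fold (edgeR adjusted p = 0.000918). The immediate early and dissociation stress list had 6 of 16 tested genes higher and 0 lower, and 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0019; adjusted p = 0.768 with an estimated correlation). Nr4a1 and Socs3 rose 2.95-fold and 2.57-fold, with edgeR adjusted p values of 0.00185 and 0.00161. In depleted and steady-state RPF, Fos was at 3092 ± 984 and 1917 ± 751 CPM (edgeR adjusted p = 0.146, with a range of 0.0342 to 0.493 across the alternatives). Egr1 was at 2496 ± 180 and 1722 ± 499 CPM (edgeR adjusted p = 0.0722, with a range of 0.00341 to 0.697 across the alternatives).

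The 8 tested spleen patterning transcription factors had 0 higher and 5 lower, and 6 lower when adjusted over the list alone (camera adjusted p = 0.00428; adjusted p = 0.0883 with an estimated correlation). Tcf21 (ENSMUSG00000045680, chromosome 10, 22817281 to 22820174), needed for spleen formation, fell 3.36-fold from 716 ± 85.3 to 213 ± 52.1 CPM (edgeR adjusted p = 0.00363). Nkx3-2 fell 3.85-fold to 17.8 ± 0.765 CPM (edgeR adjusted p = 0.0049), and Nr2f2 and Meis1 were among the others that passed the test. Tlx1, without which the spleen does not form, was at 408 ± 33.1 CPM before and 229 ± 27.4 CPM after depletion (edgeR adjusted p = 0.0637, with a range of 6.62e-06 to 0.296 across the alternatives). Nkx2-5 was at 39.4 ± 9.31 and 31.6 ± 2.83 CPM (edgeR adjusted p = 0.522).

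The myeloid growth factor list went both ways, with 4 of 8 tested genes higher and 3 lower, and 4 and 4 when adjusted over the list alone (camera adjusted p = 0.865). Its median log2 fold change was 0.05 and its mean 1.80, while camera ranked it downward. Csf1 (ENSMUSG00000014599, chromosome 3, 107741048 to 107760469) rose by 1.13 on the log2 scale (SE 0.22, edgeR adjusted p = 0.00603), and Kitl rose from 262 ± 69.7 to 540 ± 71.6 CPM (edgeR adjusted p = 0.0172). Csf3 and Csf2 had 0 counts at steady state. Gas6, a bridging ligand for apoptotic cells, fell 6.05-fold from 949 ± 149 to 157 ± 40.7 CPM (edgeR adjusted p = 9.97e-05). Cxcl12, which retains haematopoietic cells in their niches, fell from 18800 ± 604 to 9842 ± 1280 CPM (edgeR adjusted p = 0.000426), and Flt3l passed the test in the same direction. Il34, the second ligand of the CSF1 receptor, was at 230 ± 31.6 CPM at steady state and 102 ± 31.8 CPM after depletion (edgeR adjusted p = 0.0586, and from 0.00257 to 0.174 across the alternatives).

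The lymphoid zone stroma list had 4 of 16 tested genes higher and 4 lower, the same when adjusted over the list alone (camera adjusted p = 0.425). Ch25h, which makes the oxysterol 25-hydroxycholesterol, rose 65.4-fold from 6.18 ± 3.44 to 407 ± 133 CPM (edgeR adjusted p = 0.00031). Cxcl13, the B cell attractant, rose 2.40-fold to 173 ± 52.1 CPM (edgeR adjusted p = 0.00559), and Icam1 rose as well. Tnfsf11, encoding RANKL, rose from 3 counts in all to 4.95 ± 1.14 CPM (edgeR adjusted p = 9.97e-05), a ratio of 215 with a 95% counting interval of 73.3 to 1050. Il7, a survival factor for lymphocytes, fell 3.35-fold from 30.0 ± 12.1 to 8.97 ± 2.27 CPM (edgeR adjusted p = 0.0049), and Flt3l, Tnfsf13b and Enpp2 also fell. Ccl19 was at 12.9 ± 0.161 and 18.4 ± 7.21 CPM (edgeR adjusted p = 0.187), and Ccl21a at 0.646 ± 0.543 and 0.572 ± 0.0836 CPM (edgeR adjusted p = 0.894), in depleted and steady-state RPF. Ccl21a has near-identical copies in the genome, so its counts are uncertain. The summed B cell and plasma cell markers held 0.0146% of counts after depletion and 0.0413% at steady state (exact permutation p = 0.1).

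Matrix genes were split, with 7 of 25 tested genes higher and 12 lower, and 8 and 14 when adjusted over the list alone (camera adjusted p = 0.777). The basement membrane collagens Col4a1 and Col4a2 rose 4.09-fold to 6787 ± 290 CPM and 3.81-fold to 3445 ± 116 CPM, at edgeR adjusted p values of 9.97e-06 and 8.74e-06. Thbs1 and Lox rose too, while the fibrillar collagen gene Col1a2 fell from 1855 ± 73.2 to 806 ± 123 CPM and Col14a1 from 2805 ± 129 to 1165 ± 219 CPM. The complement list had 1 of 10 tested genes higher and 5 lower, and 1 and 6 when adjusted over the list alone (camera adjusted p = 0.175). Cfb rose 2.89-fold (edgeR adjusted p = 0.000633), and C1s1, C2, C4b and Serping1 were among the genes that fell. Pdgfrb, a receptor of stromal and mural cells, rose by 1.31 on the log2 scale to 2331 CPM from 942 CPM (edgeR adjusted p = 4.89e-05), and Pdgfra was at 442 and 358 CPM (edgeR adjusted p = 0.219).

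Iron and haem genes also moved in both directions, with 6 of 16 tested genes higher and 4 lower, and 6 and 6 when adjusted over the list alone (camera adjusted p = 0.122). Cp, the ferroxidase ceruloplasmin, rose 4.92-fold to 2602 ± 147 CPM (edgeR adjusted p = 1.03e-05), and the metal importer Slc39a14 rose 8.40-fold (edgeR adjusted p = 0.000121). The haem oxygenase gene Hmox1 rose from 138 ± 31.5 to 406 ± 162 CPM and Fth1, ferritin heavy chain, from 2438 ± 320 to 5334 ± 332 CPM. Slc40a1 (ENSMUSG00000025993, chromosome 1, 45908068 to 45926523), the iron exporter ferroportin, fell by 3.95 on the log2 scale from 2570 ± 604 to 166 ± 27.4 CPM (edgeR adjusted p = 0.0129). Without depleted replicate 2 its edgeR adjusted p was 0.0537, and with no filter on low counts 0.0654, the highest of a range from 5.51e-06 across the alternatives. Hfe fell from 327 ± 17.4 to 71.5 ± 16.2 CPM, and Blvrb and Nqo1 passed the test in that direction. Macrophages of the red pulp express Slc40a1 too, and the sum of 13 of their markers was at 203.2 CPM at steady state and 7.18 CPM after depletion.

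The remaining response lists were not called by camera. The interferon list had 3 of 20 tested genes higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.175). These were Cxcl10 (6.08-fold, edgeR adjusted p = 0.00578), Gbp2 (2.51-fold, edgeR adjusted p = 0.00241) and Usp18. MHC class I presentation had 1 of 12 higher, Psme2, and 2 lower, or 1 and 3 when adjusted over the list alone (camera adjusted p = 0.425). Tapbp and Psmb9 fell 1.64-fold and 3.10-fold, at edgeR adjusted p values of 0.00218 and 0.00366. Apoptotic cell uptake had 2 of 13 higher and 3 lower, or 2 and 4 when adjusted over the list alone (camera adjusted p = 0.643), with a median log2 fold change of 0.09 and a mean of -0.31. Anxa1 rose 3.59-fold (edgeR adjusted p = 0.00139) and Itgav rose as well, while Gas6, Pros1 and Lrp1 fell.

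Hypoxia and glycolysis had 6 of 15 higher and 3 lower, the same when adjusted over the list alone (camera adjusted p = 0.0908). The glycolytic enzyme Eno1 and the vasodilator peptide Adm rose 2.14-fold and 2.83-fold, at edgeR adjusted p values of 0.000312 and 0.000329, and Vegfa, P4ha1 and Ndrg1 fell. The unfolded protein response list had 2 of 14 higher and 1 lower, Pdia4, unchanged when adjusted over the list alone (camera adjusted p = 0.149). Its 2 higher genes, Atf4 (2.84-fold, edgeR adjusted p = 6.25e-05) and Asns (3.92-fold, edgeR adjusted p = 0.00104), belong to the amino acid response. The cell cycle list had 1 of 18 higher, Tyms, and 0 lower (camera adjusted p = 0.535), and the cholesterol synthesis list 2 of 14 higher, Sqle among them, and 0 lower (camera adjusted p = 0.425). Adjusted over the list alone, each of these 2 lists had 1 gene higher.

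Among genes with large changes, Mmp8 (ENSMUSG00000005800), a neutrophil-type collagenase, rose from 0 counts to 71.3 ± 26.5 CPM, at least 3130-fold against a floor of 3 counts over the group (edgeR adjusted p = 0.000334). On the same floor, Tmem132e, Csf3 and Mmp13, a collagenase, were at least 634-fold, 512-fold and 497-fold higher, at edgeR adjusted p values of 0.0307, 0.000457 and 0.00511. Aldh1a2, which makes retinoic acid, rose from 1 count to 26.0 ± 3.69 CPM (edgeR adjusted p = 5.45e-05), a ratio of 3360 with a 95% counting interval from 603 to 133000. Genes with large falls included Tro, C1qa and Cd5l, which had 0 counts after depletion and were at least 548-fold, 520-fold and 524-fold lower, at edgeR adjusted p values of 0.000155, 0.00134 and 0.00253. Mrap2 and Slc11a1 fell from 34.5 ± 13.8 and 15.5 ± 5.37 CPM to 1 count each, at edgeR adjusted p values of 1.46e-05 and 3.41e-05. Their ratios were 3750 (95% counting interval 673 to 148000) and 1890 (338 to 74600).

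Markers of other cell types were measured in the same libraries. Of 13 tested red pulp macrophage markers, 10 fell and 0 rose, and 11 fell when adjusted over the list alone (camera adjusted p = 5.33e-07; adjusted p = 0.0386 with an estimated correlation). The median log2 fold change of the list was -6.74, and the same with the genes at 0 counts set to their bound. C1qb was at 48.4 ± 8.78 CPM at steady state and 0.423 ± 0.709 CPM after depletion, and Hpgd at 50.3 ± 11.1 and 2.27 ± 1.69 CPM. Of the monocyte list, Plac8 was at 534 CPM after depletion and 302 CPM before, and Lyz2 at 9.40 and 28.2 CPM (1 of 5 higher and 1 lower, camera adjusted p = 0.643). Neutrophil markers had 0 of 8 called (camera adjusted p = 0.175), with Ngp at 6.66 and 56.6 ± 71.9 CPM and Mpo at 4.59 and 44.7 CPM. The B cell and plasma cell list had 2 of 7 lower, Ighm (22.4 from 130 CPM) and Jchain (camera adjusted p = 0.175), and Cd74 stood at 77.5 and 103 CPM. Erythroid genes had 0 of 10 called (camera adjusted p = 0.865), with Hbb-bs at 254 and 228 CPM and Hbb-bt at 98.3 and 66.1 CPM. The T and NK cell list had 0 of 4 called (camera adjusted p = 0.777), with Lck and Nkg7 at 0.507 and 0.188 CPM after depletion. Megakaryocyte and platelet markers had 1 of 5 higher, Pf4 (38.9 from 12.8 CPM), and Itga2b was at 3.32 and 3.84 CPM (camera adjusted p = 0.865).

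Blood endothelial markers had 1 of 11 lower, Tek (17.2 from 90.9 CPM), with Plvap at 309 and 376 CPM (camera adjusted p = 0.425), and lymphatic endothelial markers had 0 of 4 called (camera adjusted p = 0.915), with Prox1 and Flt4 at 2.17 and 1.06 CPM at steady state. The pericyte list had 2 of 6 higher, Mcam and Notch3, and 2 lower, Kcnj8 and Abcc9 (camera adjusted p = 0.865). Mcam rose from 15.6 ± 2.68 to 209 ± 17.6 CPM, Notch3 was at 192 and 105 CPM, and Kcnj8 fell from 435 ± 79.0 to 48.4 ± 17.8 CPM. The adventitial fibroblast list had 3 of 9 lower, Ly6a (301 from 908 CPM), Ly6c1 (92.5 from 414 CPM) and Clec3b (camera adjusted p = 0.0614). Mesothelial and adipocyte markers had 0 of 5 called each (camera adjusted p = 0.662 and 0.915), with Gpm6a at 3.31 and 14.2 CPM, Lpl at 4.54 and 6.61 CPM and Pparg at 3.60 and 3.87 CPM. Msln, not tested, was at 0 and 2.21 CPM. The pancreatic acinar, Schwann cell and skeletal muscle lists had fewer than 3 tested genes each, none of them called by edgeR. Among their highest genes after depletion were Cela1 and Cpa1 at 1.52 and 1.73 CPM, Mbp at 6.20 CPM, and Mylpf and Ckm at 0.812 and 0.0723 CPM.

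Genes behind the sort and the depletion were checked separately. Wt1 (ENSMUSG00000016458) was at 34.4 CPM after depletion and 62.1 CPM before (edgeR adjusted p = 0.324, with a range of 0.012 to 0.56 across the alternatives). Vcam1 was at 1035 and 1590 CPM (edgeR adjusted p = 0.0364), a call lost without 4 of the 6 libraries in turn, with adjusted p values up to 0.123. Pdpn, which encodes gp38, was at 0.0733 and 0.0981 CPM (edgeR adjusted p = 0.647) and Pecam1, which encodes CD31, at 0.956 and 3.87 CPM (edgeR adjusted p = 0.377). Ptprc, which encodes CD45, was at 0.0862 and 6.23 CPM (edgeR adjusted p = 0.144, with a range of 0.0177 to 0.282 across the alternatives). Fcgr1, which encodes CD64, was too low to be tested, at 0 counts after depletion and 0.879 ± 0.842 CPM before. Hbegf, whose human protein is the diphtheria toxin receptor, rose 3.63-fold to 58.2 CPM (edgeR adjusted p = 0.00336).

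**Figure D2:**
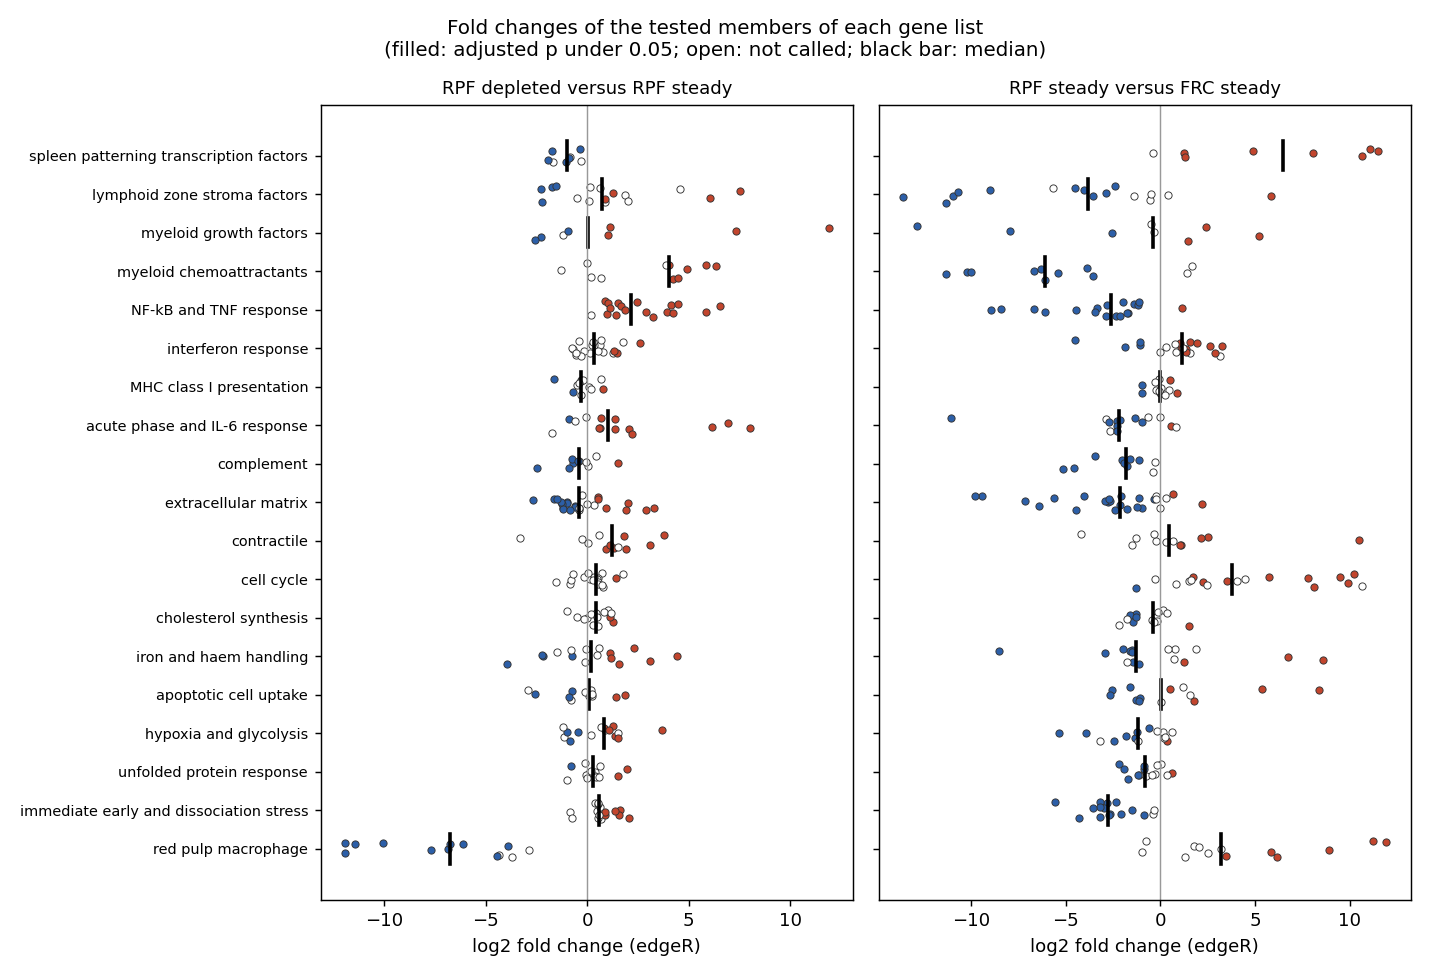
Log2 fold changes of the tested genes of each list, with points for genes and the zero line for no change. The NF-kB and TNF response genes lie to the right after depletion, with 17 of 18 called higher, and 17 of them lie lower in steady-state RPF than in FRC.

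These counts depended on the scaling, the test and single libraries, and more genes were lower than higher with RLE scaling (1564 higher and 1592 lower), with upper quartile scaling (1463 and 1688) and in DESeq2 (1999 and 2310). A test against a 1.5-fold change left 855 genes higher and 815 lower, and without RPF steady replicate 2 the number lower was 968. The calls of Tmem132e, Csf2, Nr2f2 and P4ha1 were lost without any 1 of the 6 libraries (edgeR adjusted p up to 0.143), those of Lyz2, Plac8, Pf4, Jchain, Sqle, Flt3l, Tyms, Notch3, Abcc9, Tek, Enpp2, Meis1, Blvrb, Nqo1, Clec3b and Psme2 without 3 to 5 of them (up to 0.156), those of Ighm, Pros1 and Serping1 without 2 of them (up to 0.0568), and that of Kitl without depleted replicate 1 (0.0608).

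Comparing RPF with FRC at steady state asks what distinguishes red pulp fibroblasts from the reticular stroma of lymph nodes. RPF carried the transcription factors of the spleen primordium, which FRC had at or near 0. Tlx1 was at 408 ± 33.1 CPM in RPF and 0.182 ± 0.178 CPM in FRC (n = 3), and Tcf21 was 264-fold higher in RPF. The ligands of the CSF1 receptor were higher in RPF, Csf1 2.76-fold and Il34 37.4-fold, while Csf2, Csf3 and Gas6 were higher in FRC. FRC had more mRNA of lymphocyte chemokines, inflammatory chemokines, extracellular matrix and complement, the last at adjusted p = 0.0724 with an estimated correlation, with Ccl19 23.0-fold and C3 35.6-fold higher. The immediate early and dissociation stress list was higher in FRC too (adjusted p = 0.0703 with an estimated correlation). Its median log2 fold change was -2.77, beside -2.58 for the NF-kB and TNF response list. Handling stress may contribute to the inflammatory genes of FRC and was not tested for this comparison. In all, edgeR called 1734 genes higher in RPF and 2174 higher in FRC of 15103 tested, and 1352 and 1667 of these were beyond 2-fold.

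Of the 8 tested spleen patterning transcription factors, 7 were higher in RPF and 0 lower, also when adjusted over the list alone (camera adjusted p = 1.42e-19; adjusted p = 0.00222 with an estimated correlation). Tlx1 (ENSMUSG00000025215, chromosome 19, 45150680 to 45156943) differed by 11.07 on the log2 scale (SE 0.45, edgeR adjusted p = 9.78e-07), and Tcf21 by 8.04 (SE 0.41, edgeR adjusted p = 2.6e-06). Nkx2-5 was at 39.4 ± 9.31 CPM in RPF and had 2 counts in FRC (edgeR adjusted p = 1.92e-06), a ratio of 1810 with a 95% counting interval of 501 to 15000. Nkx3-2 was at 68.5 ± 17.0 CPM with 2 counts in FRC, a ratio of 3150 (871 to 26000). Intervals and floors cover counting error only.

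The lymphoid zone stroma list had 10 of 16 tested genes higher in FRC and 1 higher in RPF, and 11 and 2 when adjusted over the list alone (camera adjusted p = 6.24e-13; adjusted p = 0.00305 with an estimated correlation). Enpp2, which makes lysophosphatidic acid, was at 6270 ± 398 CPM in FRC and 12.0 ± 4.74 CPM in RPF (521-fold, edgeR adjusted p = 3.62e-06), and Icam1 was 7.41-fold higher in FRC (edgeR adjusted p = 3.04e-06). The T zone chemokines Ccl19 and Ccl21a were at 423 ± 54.9 and 1134 ± 98.2 CPM in FRC and at 18.4 ± 7.21 and 0.572 ± 0.0836 CPM in RPF, with edgeR adjusted p values of 6.69e-06 and 3.73e-06. Cxcl13 was 16.2-fold and Il7 5.33-fold higher in FRC, at edgeR adjusted p values of 9.45e-06 and 0.00067. The member higher in RPF was the Notch ligand Dll1, at 274 ± 7.42 against 4.76 ± 4.14 CPM (edgeR adjusted p = 0.000872). The lymphatic endothelial list, which also holds Ccl21a, had that gene alone called of 4 tested (camera adjusted p = 0.0956), and Prox1 was at 4.43 CPM in FRC and 2.17 CPM in RPF.

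Myeloid growth factors went both ways, with 3 of 8 higher in RPF and 3 higher in FRC, or 3 and 4 when adjusted over the list alone (camera adjusted p = 0.917). Their median log2 fold change was -0.40 and their mean -1.88, while camera ranked the list upward. Csf1 was at 1404 ± 142 CPM in RPF and 508 ± 156 CPM in FRC (edgeR adjusted p = 0.0012), Il34 at 230 ± 31.6 and 6.15 ± 3.43 CPM (edgeR adjusted p = 4.56e-05), and Kitl at 262 ± 69.7 and 49.5 ± 12.8 CPM. Gas6 was 5.85-fold higher in FRC (edgeR adjusted p = 4.22e-05), as were Csf3 and Csf2, which had 0 counts in RPF. Cxcl12 was the most abundant member in both, at 18800 ± 604 CPM in RPF and 23570 ± 1280 CPM in FRC (edgeR adjusted p = 0.0527). It was called higher in FRC in 3 of 16 alternatives, with a lowest adjusted p of 0.00973.

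Myeloid chemoattractants were higher in FRC for 9 of 11 tested genes and higher in RPF for 0, also when adjusted over the list alone (camera adjusted p = 4.07e-13; adjusted p = 0.0155 with an estimated correlation). Ccl2 was 67.8-fold higher in FRC at 1372 ± 177 CPM (edgeR adjusted p = 1.08e-05), and Ccl7 1200-fold at 1901 ± 147 CPM (edgeR adjusted p = 5.62e-06). The eosinophil attractant Ccl11 was at 573 ± 40.1 CPM in FRC and 0.217 ± 0.103 CPM in RPF, and Cxcl2 was 79.9-fold higher in FRC, at edgeR adjusted p values of 1.58e-06 and 4.5e-06. The NF-kB and TNF response list had 17 of 18 genes higher in FRC and 1, Traf1, higher in RPF, also when adjusted over the list alone (camera adjusted p = 5.21e-28; adjusted p = 0.00305 with an estimated correlation). Ptgs2 was 487-fold higher in FRC at 1507 ± 229 CPM (edgeR adjusted p = 1.22e-07), and Il6 was at 1101 ± 112 CPM against 3.20 ± 1.48 CPM.

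The immediate early and dissociation stress list moved with these groups, with 14 of 16 genes higher in FRC and 0 higher in RPF, also when adjusted over the list alone (camera adjusted p = 5.68e-19; adjusted p = 0.0703 with an estimated correlation). Egr1 was 9.11-fold higher in FRC at 15690 ± 1549 CPM (edgeR adjusted p = 6.93e-06), Zfp36 9.23-fold (edgeR adjusted p = 5.15e-06), and Fos was at 8091 ± 1292 against 1917 ± 751 CPM. The mitochondrial share of counts was 2.07% ± 0.148 in FRC and 0.628% ± 0.102 in RPF, at an exact permutation p of 0.1, and 7 of 8 tested mitochondrial genes were higher in FRC. The 20 most abundant genes held 23.7% of counts in FRC and 14.3% in RPF. The acute phase and IL-6 response list had 8 of 14 genes higher in FRC and 1, Il6st, higher in RPF, also when adjusted over the list alone (camera adjusted p = 5.92e-06; adjusted p = 0.0729 with an estimated correlation). Saa3 was at 108 ± 55.2 CPM in FRC and 0.0455 ± 0.0162 CPM in RPF (edgeR adjusted p = 1.03e-05), and Socs3 was 6.52-fold higher in FRC (edgeR adjusted p = 2.45e-05).

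Complement and matrix genes were higher in FRC. The complement list had 8 of 10 tested genes higher in FRC and 0 higher in RPF, also when adjusted over the list alone (camera adjusted p = 6.52e-10; adjusted p = 0.0724 with an estimated correlation). C3, the central complement component, was the most abundant gene of FRC libraries, at 57510 ± 6243 against 1617 ± 355 CPM (edgeR adjusted p = 4.5e-06), and C1ra was 4.15-fold higher (edgeR adjusted p = 9.55e-06). The matrix list had 19 of 25 genes higher in FRC and 2, Col14a1 and Bgn, higher in RPF, or 20 and 2 when adjusted over the list alone (camera adjusted p = 6.02e-24; adjusted p = 0.00305 with an estimated correlation). Col6a1 and Thbs1 were 48.9-fold and 84.6-fold higher in FRC, both at an edgeR adjusted p of 4.13e-07. The small proteoglycan gene Dcn was at 26900 ± 2397 CPM in FRC and 30.6 ± 16.4 CPM in RPF, and Lum at 5418 ± 626 and 7.94 ± 4.61 CPM. Pdgfra was 1.88-fold higher in FRC (edgeR adjusted p = 0.00272) and Pdgfrb 1.83-fold higher in RPF (edgeR adjusted p = 0.000145).

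The contractile list had 5 of 12 genes higher in RPF, Smtn, Actg2, Tagln, Tpm1 and Mylk, and 0 higher in FRC, or 5 and 3 when adjusted over the list alone (camera adjusted p = 0.0553). Smtn was 4.44-fold higher (edgeR adjusted p = 1.69e-05), Actg2 at least 156-fold (edgeR adjusted p = 0.00015), and Acta2 was at 255 ± 85.1 CPM in RPF and 633 ± 473 CPM in FRC (edgeR adjusted p = 0.084, and 0.0393 without FRC replicate 3, with a range of 0.0393 to 0.328 across the alternatives). The cell cycle list had 9 of 18 genes higher in RPF and 1, Pcna, higher in FRC, or 13 and 1 when adjusted over the list alone (camera adjusted p = 0.000639; adjusted p = 0.22 with an estimated correlation). Ccna2 was at 16.5 ± 7.29 CPM in RPF with 1 count in FRC (edgeR adjusted p = 6.68e-05), a ratio of 1500 (95% counting interval 270 to 59500). Ccnb2 was at 6.68 ± 4.15 CPM with 2 counts in FRC (edgeR adjusted p = 0.000506), a ratio of 330 (91.2 to 2730). Erythroid markers moved in the same direction, with 5 of 10 higher in RPF, among them Slc4a1, Klf1, Car1 and Epor, and 7 when adjusted over the list alone (camera adjusted p = 7.98e-06; adjusted p = 0.22 with an estimated correlation). Slc4a1 was at 49.8 ± 27.5 CPM in RPF with 1 count in FRC, Hbb-bs at 228 ± 155 and 24.6 ± 24.1 CPM, and Hba-a1 at 65.2 and 10.6 CPM.

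The interferon list had 9 of 20 genes higher in RPF and 4 higher in FRC, or 12 and 4 when adjusted over the list alone (camera adjusted p = 0.0553). Cxcl10 and Gbp2 were 23.0-fold and 3.69-fold higher in FRC, at edgeR adjusted p values of 0.000318 and 0.000258, with Usp18 and Irgm1, while Ifit3, Irf7 and Oas1a were among those higher in RPF. MHC class I presentation had 2 of 12 higher in RPF, B2m and Psmb9, and 2 higher in FRC, Tapbp and Tap2, also when adjusted over the list alone (camera adjusted p = 0.898). B2m was 1.41-fold higher in RPF (edgeR adjusted p = 0.00374) and Tapbp 1.95-fold higher in FRC (edgeR adjusted p = 0.000282). Iron and haem handling had 3 of 16 higher in RPF and 8 higher in FRC, or 6 and 9 when adjusted over the list alone (camera adjusted p = 0.0956). The 3 were Slc40a1, at 2570 ± 604 against 6.77 ± 9.21 CPM (edgeR adjusted p = 0.000478), Bmp6, which signals body iron, at 167 ± 30.4 against 1.58 ± 1.40 CPM (edgeR adjusted p = 0.000322), and Hfe. Cp and Fth1 were 3.04-fold and 2.83-fold higher in FRC, at edgeR adjusted p values of 1.71e-05 and 2.07e-05.

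Apoptotic cell uptake had 4 of 13 higher in RPF, Cd36, Axl, Mertk and Stab2, and 6 higher in FRC, also when adjusted over the list alone (camera adjusted p = 0.549). Its median and mean log2 fold changes were 0.04 and 0.66, while camera ranked it downward. Cd36, a scavenger receptor, was at 939 ± 182 CPM in RPF and 2.79 ± 1.77 CPM in FRC (335-fold, edgeR adjusted p = 1.11e-05). Hypoxia and glycolysis had 7 of 15 higher in FRC and 1, Aldoa, higher in RPF (camera adjusted p = 0.00988; adjusted p = 0.2 with an estimated correlation), and the unfolded protein response 6 of 14 higher in FRC and 1, Xbp1, higher in RPF (camera adjusted p = 0.00624; adjusted p = 0.327 with an estimated correlation). Both had the same counts when adjusted over the list alone. Adm and Hk2 were 15.1-fold and 40.9-fold higher in FRC, at edgeR adjusted p values of 1.46e-06 and 0.000698, and Atf4 and Hspa5 4.62-fold and 3.24-fold, at 3.04e-06 and 8.19e-05. Cholesterol synthesis had 4 of 14 higher in FRC, among them Hmgcs1, Sqle and Cyp51, and 1, Mvd, higher in RPF, or 7 and 1 when adjusted over the list alone (camera adjusted p = 0.186). Hmgcs1 was 2.48-fold higher in FRC (edgeR adjusted p = 0.00945).

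Genes with large differences in favour of RPF included Pla2g2f, a secreted phospholipase, Fam151a, the adrenergic receptor Adra2b and the ATP-gated channel P2rx2. They had 0 counts in FRC and were at least 1430-fold, 979-fold, 854-fold and 489-fold higher in RPF, at edgeR adjusted p values of 0.00034, 0.000158, 0.00175 and 0.0184. Chrna6, a nicotinic receptor subunit, was at 67.6 ± 20.1 CPM with 1 count in FRC (edgeR adjusted p = 0.00559), a ratio of 6260 (95% counting interval 1120 to 247000). In the other direction, Bst1, Csf3 and Hoxd8 had 0 counts in RPF and were at least 1780-fold, 1030-fold and 1040-fold lower in RPF, at edgeR adjusted p values of 6.5e-05, 0.000199 and 0.00037. Fgf10 was at 151 ± 12.3 CPM in FRC with 2 counts in RPF (edgeR adjusted p = 4.13e-07), a ratio of 9680 (2680 to 80000). The most abundant gene of all 6 RPF libraries was Coch, at 29560 ± 2023 CPM in steady-state RPF and 31.8 ± 30.4 CPM in FRC, a gene chosen after its values were seen.

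Markers of other cell types differed as well. Of 13 tested red pulp macrophage markers, 6 were higher in RPF and 0 lower, or 9 and 0 when adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.151 with an estimated correlation), with Hpgd at 50.3 and 20.1 CPM and C1qb at 48.4 and 5.28 CPM. Monocyte markers had 2 of 5 higher in RPF, Plac8 (302 against 143 CPM) and Chil3, with Lyz2 at 28.2 and 20.3 CPM (camera adjusted p = 0.222). Neutrophil markers had 3 of 8 higher in RPF, Ngp, Mpo and Camp (camera adjusted p = 0.0801), with Mpo at 44.7 and 0.278 CPM. The B cell and plasma cell list had 1 of 7, Cd74, higher in FRC at 261 against 103 CPM, and Igkc was at 602 ± 836 and 90.1 CPM (camera adjusted p = 0.81). Nkg7 was the 1 of 4 T and NK cell genes higher in RPF (camera adjusted p = 0.894), with Trac at 0.648 and 13.3 CPM and Lck at 1.46 and 5.51 CPM in RPF and FRC. Megakaryocyte and platelet markers had 2 of 5 higher in RPF, Pf4 (12.8 against 4.17 CPM) and Ppbp, with Itga2b at 3.84 and 7.34 CPM (camera adjusted p = 0.232).

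Blood endothelial markers had 2 of 11 higher in RPF, Plvap (376 against 48.1 CPM) and Kdr, with Tek at 90.9 and 33.7 CPM (camera adjusted p = 0.0801). The pericyte list had 3 of 6 higher in FRC, Rgs5 (323 against 0.138 CPM), Abcc9 (1579 against 29.2 CPM) and Cspg4, and 1 higher in RPF, Kcnj8 at 435 against 179 CPM (camera adjusted p = 0.00707; adjusted p = 0.0756 with an estimated correlation). Adipocyte markers had 3 of 5 higher in FRC, Lpl (1511 against 6.61 CPM), Car3 (87.6 against 0.234 CPM) and Plin1 (camera adjusted p = 0.0123; adjusted p = 0.114 with an estimated correlation). The adventitial fibroblast list had 2 of 9 higher in RPF, Ly6a (908 against 425 CPM) and Ly6c1, and 3 higher in FRC, Has1 (977 against 1.35 CPM), Cd34 and Clec3b (camera adjusted p = 0.543). Mesothelial markers had 1 of 5, Krt8, higher in FRC (camera adjusted p = 0.558), with Gpm6a at 14.2 and 1.62 CPM and Krt18 at 0.277 and 11.2 CPM in RPF and FRC. Both tested pancreatic acinar genes, Cela1 and Cpa1, were called higher in RPF at 4.12 and 1.63 CPM with 0 counts in FRC. Neither the 2 tested Schwann cell genes nor the 1 tested skeletal muscle gene was called by edgeR, with Mbp at 7.24 and 8.56 CPM, S100b at 0.0197 and 1.71 CPM, Mylpf at 0.523 and 0.252 CPM and Ckm at 0.0481 and 0.486 CPM.

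Of 6 tested genes behind the sort and the depletion, 1 was called higher in RPF and 2 higher in FRC, or 1 and 3 when adjusted over the list alone. Wt1 was 37.7-fold higher in RPF at 62.1 ± 2.57 CPM (edgeR adjusted p = 0.00041), and Pdpn 682-fold higher in FRC at 74.1 ± 3.79 CPM (edgeR adjusted p = 1.08e-05). Vcam1 was at 2983 CPM in FRC and 1590 CPM in RPF (edgeR adjusted p = 0.00541), and Hbegf, at 30.9 CPM in FRC, had a log2 fold change of -0.95 (edgeR adjusted p = 0.0531). Pecam1 was at 6.69 and 3.87 CPM (edgeR adjusted p = 0.737), and Ptprc at 2.58 and 6.23 CPM (edgeR adjusted p = 0.729). Fcgr1 had 1 count in FRC and was not tested.

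Organ, tissue dissection and gate differ together between the groups. Upper quartile scaling moved the median log2 fold change of all genes from -0.02 to 0.14 and gave 2158 genes higher in RPF and 1821 higher in FRC, a test against a 1.5-fold change left 1095 and 1447, and leaving out at least 1 library ended the calls of Usp18, Psmb9, Chil3, Camp, Nkg7, Csf2, Cela1, Mpo, Aldoa, Xbp1, Cyp51, Traf1, Kcnj8, Cd74, Cspg4, Tap2, Mvd, Nkx2-3, Irgm1, Cpa1 and Pf4 (edgeR adjusted p up to 0.159).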

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

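The term for Y-linked reads and the count without genes of other cell types were chosen after seeing the data; the other alternatives were chosen before. No called gene was called in the opposite direction in any setting. Between depleted and steady-state RPF the settings other than leaving out a library kept from 52.6% to 99.3% of the called genes, and between RPF and FRC from 65% to 99.5%. A test against a 1.5-fold change gave 855 genes higher and 815 lower after depletion, and 1095 higher and 1447 lower in RPF against FRC, because it asks for a larger change. DESeq2 gave 2310 genes lower after depletion; the cause was not tested. Leaving out 1 library at a time gave 1176 to 1287 genes higher and 968 to 1148 lower after depletion, the 968 without RPF steady replicate 2, and 1168 to 1566 higher and 1620 to 1878 lower in RPF against FRC, with fewer libraries in each fit. With an estimated correlation 3 lists were called after depletion and 5 in RPF against FRC, and fry, which does not compare a list with other genes, called 15 and 26.

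Of 2235 log2 fold changes of 140 named genes after depletion, 2031 kept direction and side of the threshold, 172 lost the call, 28 gained it and 4 changed sign. Those 4 were uncalled: Ccl21a at -0.25 in limma-voom and -0.76 without RPF depleted replicate 2, Pdpn at 0.43 without RPF steady replicate 2, and Irf1 at -0.00572 without RPF depleted replicate 2; the cause was not tested. Leaving out 1 library at a time, these genes ranged from -0.76 to 0.62, from -1.44 to 0.43 and from -0.00572 to 0.39. Of 2473 values of 155 genes in RPF against FRC, 2339 were the same, 124 lost the call, 10 gained it and 0 changed sign. With the term for Y-linked reads 1481 genes were higher and 1226 lower after depletion, and 1602 higher and 2039 lower in RPF against FRC. Without genes of other cell types, 1667 were higher and 1483 lower after depletion. Upper quartile scaling moved the median log2 fold change of all genes from -0.09 to -0.19 after depletion. The smallest depth, 25414645 counts, puts the floor of 3 counts at 0.118 CPM.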

Other observations

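The tests of handling stress, of myeloid RNA, of diphtheria toxin itself, of Slc40a1 and of sex were chosen after seeing the data, as were the annotation terms and the gene families; the tests of pan-leukocyte genes, splits and shared libraries were chosen before their results were seen.

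Depleted RPF had more mRNA of cytosolic ribosomal proteins and other genes of protein synthesis. Of 1984 Gene Ontology processes with 10 to 300 genes, 83 were enriched among genes higher after depletion (hypergeometric test, Benjamini-Hochberg adjusted). Translation had 129 of 271 genes higher (adjusted p = 7.53e-40), and ribosome biogenesis 52 of 89 (adjusted p = 2.4e-20). The hypergeometric test counts genes as independent draws, so its p values do not measure variation between libraries. Among genes lower after depletion 6 processes were enriched, led by extracellular matrix organization with 24 of 73 genes (adjusted p = 0.00101), while the fixed matrix list was not called (camera adjusted p = 0.777). Of 78 cytosolic ribosomal protein genes edgeR called 51 higher and 0 lower, with a median log2 fold change of 1.52, and 47 higher with a median of 1.42 under upper quartile scaling. All 7 genes of the CCT chaperonin, 16 of 18 tRNA synthetase genes and 29 of 53 initiation factor genes were called higher, the last with 3 lower. Of 38 proteasome subunit genes, 29 were called higher and 1 lower, so the rise was not limited to genes of protein synthesis. Of 77 mitochondrial ribosomal protein genes, 14 were called higher and 0 lower, with 16 below 0. Reads of ribosomal protein genes are shared with pseudogenes, so their counts are uncertain. With the tested genes ranked by transcript length into 3 parts of near-equal size, the short genes had 685 higher and 504 lower after depletion (median log2 fold change 0.01) and the long genes 433 higher and 503 lower (median -0.18), and a part of length in the ribosomal rise was not tested. Of 19 Hox genes, 12 were called lower in RPF than in FRC and 0 higher, and 0 were called after depletion.

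The rise of NF-kB and TNF response genes after depletion had a median log2 fold change of 2.16. Handling stress during tissue digestion stays open as a part of it, since the 16 immediate early and dissociation stress genes had a median log2 fold change of 0.599 and edgeR called 6 of them higher. RNA of myeloid cells in the sort was weighed over all 32 genes of the macrophage, monocyte and neutrophil lists and Ptprc. Their summed level was 692 CPM in the highest depleted library and 597 CPM in the lowest steady-state library, so the full sum did not decide. Plac8, the gene of these called higher by edgeR, made up most of the depleted sum, and without it these levels were 76.9 and 318.5 CPM. Of 15 pan-leukocyte genes edgeR called 0 higher, with a median log2 fold change of -1.65. Apart from Plac8, which goes the other way, these values argue against more myeloid RNA in the depleted sort. An effect of diphtheria toxin itself, for which there were 0 libraries of toxin-treated mice without the receptor transgene, and a response of the fibroblasts to the loss of macrophages may each contribute and were not told apart.

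Red pulp macrophage markers and Slc40a1 may have fallen because steady-state sorts carried macrophage RNA, although the sort was enriched for CD45-negative cells. The median log2 fold change of 15 pan-leukocyte genes was -1.65, with 3 called lower by edgeR, Aif1, Ctss and Cd53, and 0 called higher. Only Arhgdib, at 0.439, lay above 0. This direction goes with carried leukocyte RNA, but few of the falls were called, which leaves this source open for the markers. Slc40a1 kept 6.45% ± 1.07 of its steady-state level and the summed macrophage markers other than Hpgd 3.53% ± 2.87, so the shares do not part it from macrophage RNA. Against this source, Slc40a1 stood at 2570 CPM and 13 macrophage markers together at 203.2 CPM, and how much Slc40a1 a macrophage carries was not analysed here. A fall within the fibroblasts stays open.

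Sex of the pooled mice could add to the changes, since RPF steady replicate 1 and FRC replicate 1 lacked Y-linked reads. With the presence of such reads as a term in the model, 81.2% of the called genes (2578 of 3176) stayed called after depletion, which argues against sex as the main source. The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. The real split gave 3176 genes after depletion and the highest of the others 1, and for RPF against FRC 3908 and 0; in each comparison 1 split gave as many as the real one, itself.

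Genes changed after depletion overlapped with those that differ between FRC and steady-state RPF, in comparisons that share the steady-state RPF libraries. Of genes higher after depletion, 642 were also higher in FRC, where independence gives 240.5, and of those lower 372 were also lower, where it gives 172.8. In the opposite directions, 168 were higher after depletion and lower in FRC (191.9 by independence), and 301 lower after depletion and higher in FRC, also above the 216.6 of independence. In 20 simulations with no true change in any gene, at most 0 genes were called in both comparisons. With no change to find, that count was near certain beforehand and does not bear on overlap among genes that did change. The simulated covariance of the log2 fold changes from shared steady-state libraries alone was 0.644 to 0.73, where the observed value was 1.31. The observed correlation, 0.226, lay under the simulated range of 0.464 to 0.513, and how much of the overlap the shared libraries may account for stays open.

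Of all tested genes, 44.4% had no overlap between the libraries of depleted and steady-state RPF and 44.6% none between RPF and FRC, where chance gives 10%.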
